A study of Mus musculus with 3 samples.

How the data were processed

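Total RNA, depleted of ribosomal RNA, was sequenced from the cytosolic fraction of mouse bone marrow-derived macrophages (BMDM), which are macrophages grown in culture from marrow cells of C57BL/6J mice. The cells had been stimulated for 50 min with 100 ng/ml lipid A, the membrane anchor of bacterial lipopolysaccharide and a ligand of Toll-like receptor 4. The series holds 3 libraries of this 1 group. The labels mark them as separate biological replicates with separate biosample records and give all of them the same donor label, and they do not say whether these were separate animals or separate cultures. The edgeR p-values therefore measure only the spread between these samples, which may be technical, while the permutation and Fisher's exact p-values are taken over genes. No unstimulated, earlier or later sample was analysed here, and no value below is a response to lipid A.

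For each library the authors deposited a gene table and a transcript table of 1 layout and a second transcript table of another layout. The expected counts (estimated numbers of reads per gene or transcript, not whole) and the TPM values (the abundance of a transcript relative to all transcripts of the library) in them were made by the authors, separately for each library, against mm10 with GENCODE M21, per the labels and the notes deposited with each library. The layout of the first pair of tables is that of RSEM and that of the second table is that of kallisto, but the tool names and versions are not given in the sources used here, nor is the strand setting. Reads of overlapping or near-identical genes can therefore have been split between them, and such genes are named as uncertain. TPM values are shares of all RNA listed, so a few very abundant RNAs lower all other values.

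The gene tables list 55536 annotated genes, and all of their identifiers were found in the GENCODE M21 annotation (mm10), which gave names, classes and 1-based coordinates. Also listed are 26248 rows with number identifiers, all with a count of 0, spike-in standards with a count of 0, and phiX174, a bacteriophage genome. These rows were left out of every test. Gene expected counts summed to 33044910, 36769402 and 36522216 in replicates 1, 2 and 3, here also called libraries 1, 2 and 3. A count of 0 at this depth allows a level of up to 3 counts, which is 0.0908, 0.0816 and 0.0821 CPM (counts scaled to library size), and this limit covers counting error only. Library 1 was the shallowest.

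Gene levels are means of the deposited TPM with the SD over the 3 libraries. A gene counted as detected at 1 TPM or more in each library. Gene lists (23 of them, all members found) were fixed before the data were examined, with 1 gene identifier per symbol. Lists were compared by the difference in median log2(mean TPM + 1) between their genes with a two-sided permutation test of 100000 resamples over genes, Benjamini-Hochberg adjusted over 4 comparisons. Where a list had fewer than 10 members, all splits were counted in an exact permutation test, which was checked against full enumeration of small simulated lists. Genes are not independent replicates, so these p-values describe these libraries, and the SD of the difference over the 3 libraries is given beside each. The share of transcript TPM in transcripts annotated as retained intron was compared in the same way over genes at 1 TPM or more with such a transcript. Level was related to genomic length across genes with Spearman's rho and Pearson's r and permutation p-values.

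Variation between libraries was tested with edgeR 4.0.16 in R 4.3.3 on expected counts rounded to whole numbers, with filterByExpr, TMM scaling and the trended dispersion. Each gene's residual deviance was tested by chi-square goodness of fit and adjusted by the Benjamini-Hochberg method over all genes at a threshold of 0.05, and log2 CPM carry a prior count of 0.5. The members of each list among the called genes were compared with all other tested genes by a two-sided Fisher's exact test, adjusted over the 23 lists. Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the rest.

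The edgeR step was tested on simulated counts of 12231 genes with the means and sizes of the real libraries. It called 42 of 100 genes moved 2-fold in 1 library, 96 of 100 moved 4-fold and 1 of 12031 unmoved genes, at mean counts of at least 50 for the moved genes. The list permutation test, on simulated lists of 34 and 22 genes, gave p under the threshold in 2.5% of 200 draws with no shift and in 97% with a shift of 2 on the log2 scale. The percentile of a list median among random lists of matched level, used in the closing section, fell outside the central 95% for 5.1% of 2000 unshifted lists of 30 genes and for 200 of 200 lists shifted by 0.5. These were randomly picked genes with simulated noise that was independent between genes. Lists whose genes vary together can fall outside more often, and the run does not cover them. This last run was enlarged to 2000 lists after smaller runs had put a larger share of unshifted lists outside.

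Alternatives were a pseudocount of 0.1, members at 1 TPM or more, TPM rescaled to genes outside small structured, mitochondrial and ribosomal RNA, the second quantification summed per gene, TPM thresholds of 0.5 and 5, DESeq2 1.42.0 size factors, no filter on low counts, a threshold of 0.01, a median share, shares of TPM and each replicate left out in turn. The rescaling lifted the values of the 3 libraries by different factors, since the kept genes held 39.3%, 28.0% and 35.7% of TPM. The quantifications were compared at 10 TPM or more as log2 ratios with a pseudocount of 0.1, centred on each library's median, a centring chosen after the uncentred ratios were seen. Tests of variation without small structured, mitochondrial and ribosomal RNA, and on protein-coding genes alone, were chosen after seeing the data.

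Genes named in the text follow a rule fixed before the data were examined. By mean TPM it takes the 12 highest genes, the 6 highest members of the immediate early, early inflammatory, interferon stimulated, late response and macrophage identity lists and the 3 highest of every other list. It adds response, identity and reference genes named in advance (Tnf, Cxcl2, Nfkbia, Il1b, Fos, Egr1, Ifnb1, Cxcl10, Ccl5, Il6, Il12b, Nos2, Lcn2, Tlr4, Cd14, Csf1r, Adgre1, Malat1, Neat1, Actb and Gapdh). It also adds the 15 varying genes of largest range at 5 TPM or more, the 5 early genes of highest retained intron share at 5 TPM or more and the 5 genes on which both quantifications differed most at 10 TPM or more. Any other gene is named as chosen after its values were seen, and some genes are not reported here.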

Results

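The cytosolic RNA of lipid A-stimulated BMDM was measured in 3 libraries (replicates 1, 2 and 3 of 1 group), with 33044910, 36769402 and 36522216 expected counts on genes. Values are the mean ± SD over the 3 libraries in TPM, unless another unit is given. The design holds no unstimulated sample, so the comparisons set gene groups against each other within the stimulated cells and the libraries against each other.

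Small structured RNA made up most of TPM in the first quantification but not in the second. The list of abundant small noncoding RNAs held 64.3% ± 6.30 of TPM in the first but 9.10% ± 2.22 of expected counts, since these RNAs are short. In the second, a comparison of this share that was chosen after seeing the data, it held 18.5% ± 5.96 of TPM (23.6%, 19.9% and 11.9% in libraries 1, 2 and 3), and the 5 highest genes, annotated as pseudogenes and microRNA genes, held 68.5% ± 11.5. These 5 genes had 0 TPM in the first quantification, and since TPM are shares they lower all other values in the second. The share of small RNA among the molecules is therefore uncertain. Rn7s1 and Rn7s2, the RNA of the signal recognition particle, stood at 256016 ± 56547 and 257206 ± 56307 TPM, and these near-identical copies share reads, so their split is uncertain. Rn7sk, an inhibitor of transcription elongation when bound to its proteins, stood at 66705 ± 41967 TPM, and Rpph1, the RNA of ribonuclease P, at 50602 ± 34298 TPM. In the first quantification protein-coding genes took 33.2% ± 6.02 of TPM and 89.5% ± 2.37 of counts. The highest were the ferritin chains Fth1 (9362 ± 1716 TPM) and Ftl1 (9215 ± 815 TPM), lysozyme Lyz2 (6416 ± 1364 TPM), the sphingolipid activator precursor Psap (5297 ± 1091 TPM), the lysosomal protease Ctsd (4369 ± 613 TPM) and the selenium carrier Selenop (3467 ± 935 TPM). Actb and Gapdh stood at 2466 ± 512 and 415 ± 137 TPM. Genes at 1 TPM or more in each library numbered 9570, of which 9128 were protein-coding, and 458 genes reached 100 TPM. Because the small RNA share differed between libraries, the median gene had a TPM higher by 0.41 (log2) in library 1 than in library 2, higher by 0.07 in library 1 than in library 3, and a difference of -0.34 for library 2 minus library 3. The SD of a single gene's TPM includes this shift.

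The first comparison asked how genes known to respond early to lipopolysaccharide stood against those known to respond late, 50 min after lipid A was added. Early inflammatory genes had a median of 236 TPM and late response genes one of 1.10 TPM, a 215-fold ratio. Over members at 1 TPM or more in each library the late median was 7.96 TPM, the ratio was 32.3-fold and the log2 difference was 4.84 (34 and 9 genes; two-sided exact permutation p = 7.42e-05). Tnf, a cytokine that starts inflammation, stood at 1802 ± 663 TPM (ENSMUSG00000024401.14, mm10 chromosome 17, 35199381 to 35202007). The neutrophil chemoattractant Cxcl2 stood at 987 ± 285 TPM (ENSMUSG00000058427.10, chromosome 5, 90903871 to 90905938). The chemokines Ccl3 and Ccl4 stood at 994 ± 479 and 859 ± 292 TPM, Nfkbia, the inhibitor of NF-kB, at 946 ± 171 TPM and Il1b, the interleukin-1 beta precursor, at 819 ± 193 TPM. Of the 35 early inflammatory genes, 34 reached 1 TPM in each library and 18 reached 100 TPM.

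Late response genes were spread over a wide range. Of 22 members, 9 reached 1 TPM in each library, 8 were under 1 TPM in each and 2 had a count of 0 in each, which allows up to 0.0908, 0.0816 and 0.0821 CPM (counts scaled to library size). The highest were Ebi3, a subunit of interleukins 27 and 35 (30.5 ± 6.82 TPM), the costimulatory receptor Cd40 (21.2 ± 6.58 TPM), the acute phase gene Saa3 (20.2 ± 11.4 TPM) and the growth factor Csf2 (11.9 ± 3.92 TPM). Il12b stood at 7.96 ± 6.46 TPM, the siderophore binder Lcn2 at 2.37 ± 0.635 TPM and Il6 at 1.59 ± 0.854 TPM. Nos2, the inducible nitric oxide synthase, had 7, 2 and 3 counts (0.0267 ± 0.0208 TPM). The difference of medians was 6.82 ± 0.32 on the log2(TPM + 1) scale (35 and 22 genes; two-sided permutation p = 1e-05, the smallest that the permutations can give, adjusted 1e-05 over 4 comparisons). It was positive in 3 of 3 libraries.

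Immediate early genes, which encode transcription factors and feedback regulators, also stood far above the late response genes. Their median was 157 TPM, and 26 of 26 reached 1 TPM in each library. The highest were Zfp36, which destabilises cytokine mRNAs (969 ± 223 TPM), the MAP kinase phosphatase Dusp1 (588 ± 155 TPM), the AP-1 subunit Junb (570.0 ± 70.9 TPM), the G-protein regulator Rgs1 (415 ± 128 TPM), the transcription factor Egr1 (385 ± 98.6 TPM) and Klf6 (334 ± 85.7 TPM). Fos stood at 286 ± 61.6 TPM. The difference from the late response list was 6.24 ± 0.06 (26 and 22 genes; two-sided permutation p = 1e-05, adjusted 1e-05), with 3 of 3 libraries positive. Over members at 1 TPM or more it was 4.14 (26 and 9 genes; two-sided exact permutation p = 0.000485).

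The interferon arm of the response stood between these groups. Interferon stimulated genes had a median of 23.1 TPM, 10.2-fold under the early inflammatory genes, and 28 of 30 reached 1 TPM in each library, while 0 reached 100 TPM in each. The chemokine Cxcl10 stood at 171 ± 109 TPM (chromosome 5, 92346638 to 92348889) and the antiviral genes Rsad2 and Ifit2 at 108 ± 28.0 and 96.6 ± 29.7 TPM. Oasl2 and Ifit3 stood at 75.3 ± 16.8 and 74.0 ± 14.6 TPM, Ccl5 at 56.7 ± 15.8 TPM, and Ifnb1, which encodes interferon beta, at 18.7 ± 11.7 TPM (chromosome 4, 88522025 to 88522774). The early inflammatory list exceeded this list by 3.31 ± 0.27 on the log2 scale (35 and 30 genes; two-sided permutation p = 1e-05, adjusted 1e-05), in 3 of 3 libraries.

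**Figure D1:**
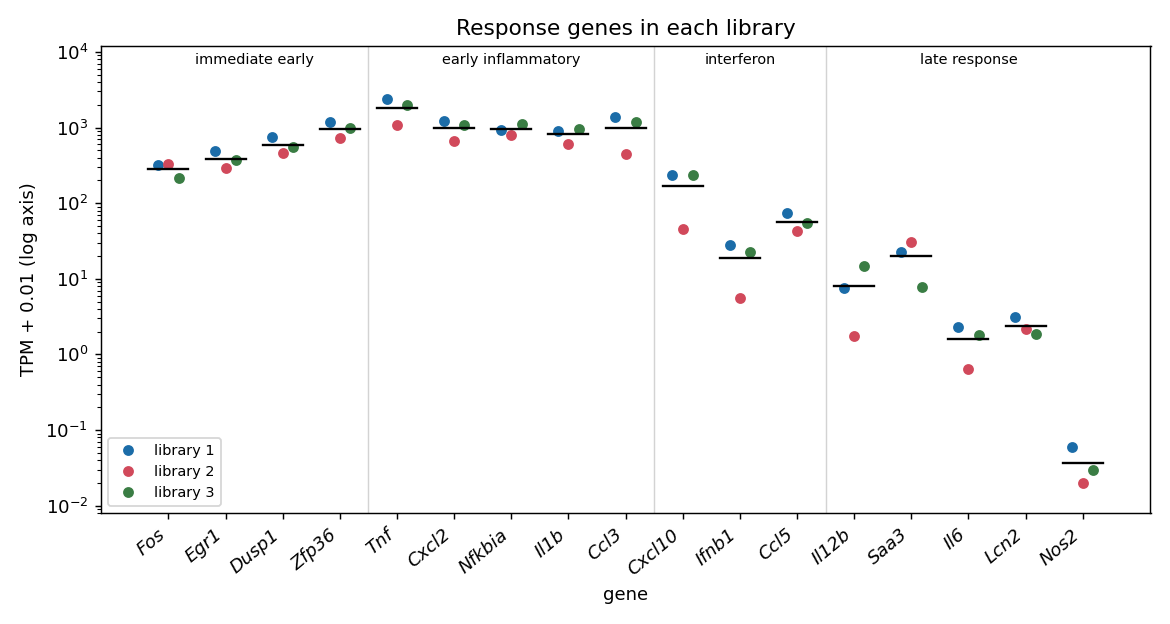
TPM + 0.01 on a log axis of 17 response genes, with 1 point per library and a bar at the mean of the 3 libraries. Tnf stood at 1802 TPM on average, Il6 at 1.59 and Nos2 at 0.0267.

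The receptor complex and signalling genes of Toll-like receptor 4 were present at moderate levels, with a median of 15.3 TPM and 28 of 28 at 1 TPM or more. Tlr4 itself stood at 30.7 ± 5.85 TPM and its co-receptor Cd14 at 522 ± 78.2 TPM. Nfkbib and Rela, an inhibitor and a subunit of NF-kB, stood at 51.8 ± 9.57 and 43.8 ± 11.0 TPM. Genes of alternative activation had a median of 1.59 TPM, with 8 of 15 at 1 TPM or more in each library, led by Tgfb1 (188 ± 33.0 TPM), the mannose receptor Mrc1 (143 ± 35.2 TPM) and Il4ra (23.1 ± 1.66 TPM).

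The next comparison asked which cells the libraries hold. Macrophage identity genes had a median of 508 TPM, with 27 of 28 at 1 TPM or more in each library, and markers of other cell types had a median of 0.0333 TPM, with 72 of 86 under 1 TPM in each. Besides Lyz2 and Ctsd, the highest were the protease Ctsb (3326 ± 1051 TPM), Apoe (2049 ± 453 TPM), the galectin Lgals3 (1923 ± 403 TPM) and Ctss (968 ± 89.1 TPM). Csf1r, the receptor for the growth factor that maintains macrophages, stood at 413 ± 164 TPM, and Adgre1, which encodes F4/80, at 185 ± 26.1 TPM. The difference was 8.92 ± 0.27 (28 and 86 genes; two-sided permutation p = 1e-05, adjusted 1e-05), positive in 3 of 3 libraries. Over members at 1 TPM or more it was 5.93 (27 and 10 genes; permutation p = 1e-05).

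Each of the 7 lists of other cell types was low. The medians were 0.0117 TPM for T and NK cells, 0.0350 TPM for B and plasma cells, 0.388 TPM for neutrophils, 0.0117 TPM for erythroid cells and megakaryocytes, 0.257 TPM for dendritic cells, 0.01 TPM for fibroblasts, stroma and endothelium and 0.0233 TPM for mast cells and basophils. A few members stood higher. Bst2 (129 ± 37.7 TPM) and the MHC class II gene H2-Aa (46.9 ± 8.27 TPM) are in the dendritic list, Il7r (39.2 ± 10.6 TPM) in the T and NK list, S100a9 (19.8 ± 2.41 TPM) and S100a8 (11.9 ± 0.376 TPM) in the neutrophil list, and Ighm (5.65 ± 1.58 TPM) in the B and plasma list. Kdr (3.00 ± 1.13 TPM), Ppbp (0.677 ± 0.215 TPM) and Kit (0.623 ± 0.306 TPM) were the highest of the stromal, erythroid and mast cell lists.

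**Figure D2:**
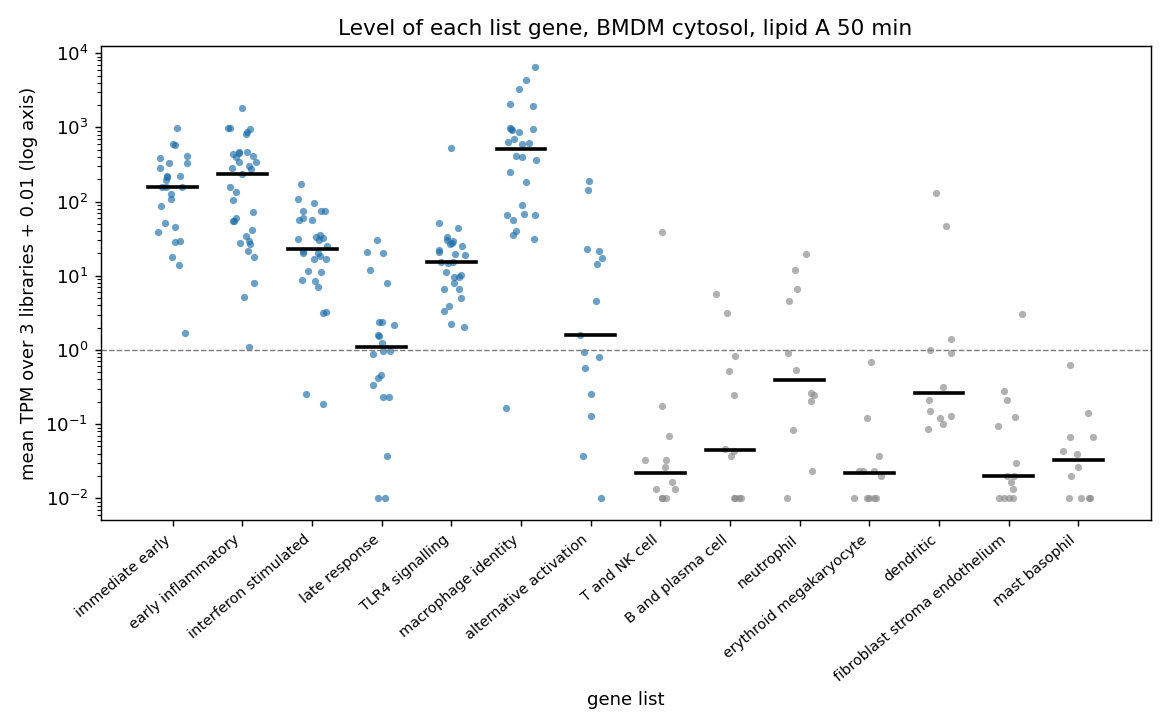
Mean TPM + 0.01 over the 3 libraries on a log axis for each gene of 14 lists, with response and macrophage lists in blue, other cell types in grey, a black bar at each list's median and a dashed line at 1 TPM. The macrophage identity list has a median of 508 TPM and the late response list one of 1.10 TPM.

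The levels of the other lists differed widely. Glycolytic genes had a median of 74.3 TPM (15 of 15 at 1 TPM or more), with the pyruvate kinase gene Pkm at 149 ± 20.9 TPM. Chaperone and stress genes had a median of 42.2 TPM (15 of 16), with Hspa8 at 608 ± 163 and the endoplasmic reticulum chaperone Hspa5 at 249.6 ± 18.1 TPM. Cholesterol synthesis genes had a median of 16.0 TPM (16 of 16), with Insig1 at 65.2 ± 25.1 and Hmgcs1 at 42.9 ± 12.3 TPM. Ribosomal protein genes had a median of 253 TPM (77 of 85), led by Rpl41 at 1187 ± 290.3 TPM. Proliferation genes had a median of 3.09 TPM (18 of 21), with the replication clamp Pcna at 86.4 ± 16.7 and Mki67 at 20.6 ± 8.15 TPM. Of the 37 mitochondrial genes, 14 reached 1 TPM in each library and 22 had a count of 0, with mt-Co1 at 1479 ± 999 TPM. Nuclear retained RNAs had a median of 0.295 TPM (4 of 12), with Malat1 at 526 ± 274 TPM, and small structured RNAs one of 29.1 TPM (11 of 14). Replication-dependent histones, whose mRNAs have no poly(A) tail, had a median of 5.55 TPM (52 of 70), with Hist1h1c at 47.2 ± 9.97 and Hist1h2bc at 42.5 ± 6.43 TPM.

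Some early genes carried much of their TPM in transcripts annotated as retaining an intron. The share was 69.6% ± 7.54 for Cd83, a surface marker of activation, 36.9% ± 3.79 for Rgs1, 28.4% ± 10.9 for the mitochondrial superoxide dismutase Sod2, 26.2% ± 11.5 for Egr3 and 19.7% ± 6.98 for the C-type lectin Clec4e. In the second quantification it was 15.7% for Egr3 and 32.1% for Clec4e, so the order of these 2 was reversed. Across genes with such a transcript, the mean share was 9.00% ± 1.29 in 30 early genes, 6.78% ± 1.03 in 11 macrophage identity genes and 6.11% ± 0.527 in all 5811 genes. The difference of 2.22 ± 2.26 percentage points was within the spread between libraries (two-sided permutation p = 0.702), and without replicate 2 it fell to 1.02 (permutation p = 0.865). Medians of the share differed by 1.82 percentage points (permutation p = 0.0475).

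Across the early genes, level had a weak negative relation to the length of the gene. Over the 61 immediate early and early inflammatory genes, from the shortest, Ier3 (1240 bp), to the longest, Nfkb1 (106893 bp), both named after their lengths were seen, with a median span of 5496 bp, Spearman's rho of level with genomic length was -0.261 (permutation p = 0.0427) and Pearson's r was -0.196 (permutation p = 0.127). These are correlations across genes, which are not independent replicates, and 1 relation was tested. Without replicate 1, 2 or 3 the permutation p of rho was 0.0641, 0.0549 and 0.0502, so the call was lost with any library left out.

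The libraries differed from each other in particular gene groups. The biological coefficient of variation was 0.147, and 203 of 12231 genes varied beyond the trend (785 at an unadjusted p under 0.05), among them 115 protein-coding genes. Of 23 lists, 6 held a larger share of called genes than the other tested genes did, by Fisher's exact test. Leaving out replicate 1, 2 or 3 gave 132, 91 and 89 varying genes, of which 99, 88 and 86 were among the 203.

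Transcripts of the mitochondrial genome were called in 13 of 14 tested members (14 when adjusted over the list alone; Fisher's exact test, adjusted p = 1.56e-21) and 13 of the 14 were highest in library 1. The cytochrome oxidase gene mt-Co1 had log2 CPM of 12.09, 11.48 and 10.15 in libraries 1, 2 and 3, and mt-Nd1, a subunit of complex I, had 9.74, 9.14 and 7.80. Of expected counts, 0.993%, 0.634% and 0.296% lay on this genome, a mean of 0.641% ± 0.349. Unprocessed pseudogenes held 0.325%, 0.251% and 0.109% of gene expected counts in libraries 1, 2 and 3. Whether they share reads with mitochondrial genes was not tested, so the mitochondrial levels are uncertain to that extent.

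Nuclear retained RNAs were highest in library 2 for 7 of 8 tested members, and 5 were called (5 over the list alone; Fisher's exact test, adjusted p = 5.19e-07). Malat1, a nuclear speckle RNA, had log2 CPM of 11.06, 12.35 and 10.07, and Neat1, the scaffold of paraspeckles, 7.71, 9.15 and 7.40. Xist, the RNA that silences an X chromosome, had 5.86, 7.39 and 6.39. The other called members were Firre and Kcnq1ot1, chosen after their values were seen. Without replicate 2 the list lost its call (Fisher's exact test, adjusted p = 1.00), as did Malat1 (edgeR adjusted p = 0.157). As a share of TPM the list took 0.0578% ± 0.0297, with 0.0687%, 0.0804% and 0.0241% in libraries 1, 2 and 3. This share covers only the 12 long noncoding RNAs of the list and is not a measure of all nuclear RNA. Rn7sk and Rpph1, for example, are outside it.

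Interferon stimulated genes were lowest in library 2 for 21 of 29 tested members and highest there for 0, and 6 were called (9 over the list alone; Fisher's exact test, adjusted p = 3.08e-05). Of the 29, 22 were highest in library 3. The median log2 deviations from each gene's mean were 0.043, -0.187 and 0.152 in libraries 1, 2 and 3. Cxcl10 had log2 CPM of 8.04, 6.15 and 8.12 (edgeR adjusted p = 4.31e-11), and Ifnb1 had 4.23, 2.36 and 4.06 (edgeR adjusted p = 4.32e-07). Ifit1, Isg15, Gbp3 and Gbp5, chosen after their values were seen, were the other called members. Without replicate 2 the list lost its call (Fisher's exact test, adjusted p = 1.00). In the late response list 2 of 19 were called (3 over the list alone; Fisher's exact test, adjusted p = 0.128). Il12b, a subunit of interleukins 12 and 23, had log2 CPM of 3.97, 2.36 and 5.02 (edgeR adjusted p = 1.27e-16) and was called with any 1 replicate left out (edgeR adjusted p up to 0.0108). Saa3 had 3.30, 4.17 and 1.96 (edgeR adjusted p = 1.22e-07). Saa3 was not called without replicate 2 (edgeR adjusted p = 0.0835) or without replicate 3 (edgeR adjusted p = 0.355). The chemokine Ccl3, with log2 CPM of 9.87, 8.76 and 9.79, was the single call among 35 early inflammatory genes (3 over the list alone; Fisher's exact test, adjusted p = 0.851).

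Cholesterol synthesis genes were highest in library 1 for 16 of 16 members, and 5 were called (10 over the list alone; Fisher's exact test, adjusted p = 2.59e-05). The list was also lowest in library 2 for 15 of 16. Its median log2 deviations from each gene's mean were 0.355, -0.320 and -0.063 in libraries 1, 2 and 3. Fdft1 and Lss, enzymes of the sterol pathway chosen after their values were seen, were among the called members. The call was lost without replicate 1 (Fisher's exact test, adjusted p = 0.449) and without replicate 2 (adjusted p = 1.00 by Fisher's exact test). Ribosomal protein genes were highest in library 3 for 70 of 79 tested members, and 11 were called (21 over the list alone; Fisher's exact test, adjusted p = 5.19e-07), Rps29 among them (735.8, 731 and 1298 TPM). This list lost its call without replicate 3 (Fisher's exact test, adjusted p = 0.490). Small structured RNAs had 3 of 10 called (5 over the list alone; Fisher's exact test, adjusted p = 0.00190). Of the 10, 8 were highest in library 2, 5 lowest in library 1 and 4 lowest in library 3, so the list had no common direction in library 3. Rn7sk and Rpph1 were called and lowest in library 3, where Rn7sk had a log2 CPM of 11.84 against 13.80 and 13.96. The third call is uncertain. Rmrp has 2 overlapping entries on chromosome 4 that share reads, of which the entry from 43492788 to 43493058 was called with 35501, 69664 and 21611 counts, while the entry from 43492783 to 43493063 had 15492, 17948 and 20241 and was not called (edgeR adjusted p = 1.00). The list lost its call without replicate 3 (Fisher's exact test, adjusted p = 1.00).

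No other list passed. Macrophage identity genes had 2 of 28 called (2 over the list alone; Fisher's exact test, adjusted p = 0.225), histones 2 of 59 (3 over the list alone; Fisher's exact test, adjusted p = 0.590), immediate early genes 1 of 26 (3 over the list alone; Fisher's exact test, adjusted p = 0.738) and dendritic genes 1 of 9 (1 over the list alone; Fisher's exact test, adjusted p = 0.357). The Toll-like receptor 4, alternative activation, cell cycle, glycolysis, chaperone and remaining cell type lists had 0 called by edgeR. Over the list alone, 2 of 6 tested neutrophil genes and 1 of 3 stromal genes were called. The T and NK list and the mast cell list had 1 tested gene each, and each was called. For a list of 1 gene this p-value of the edgeR test is unadjusted.

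**Figure D3:**
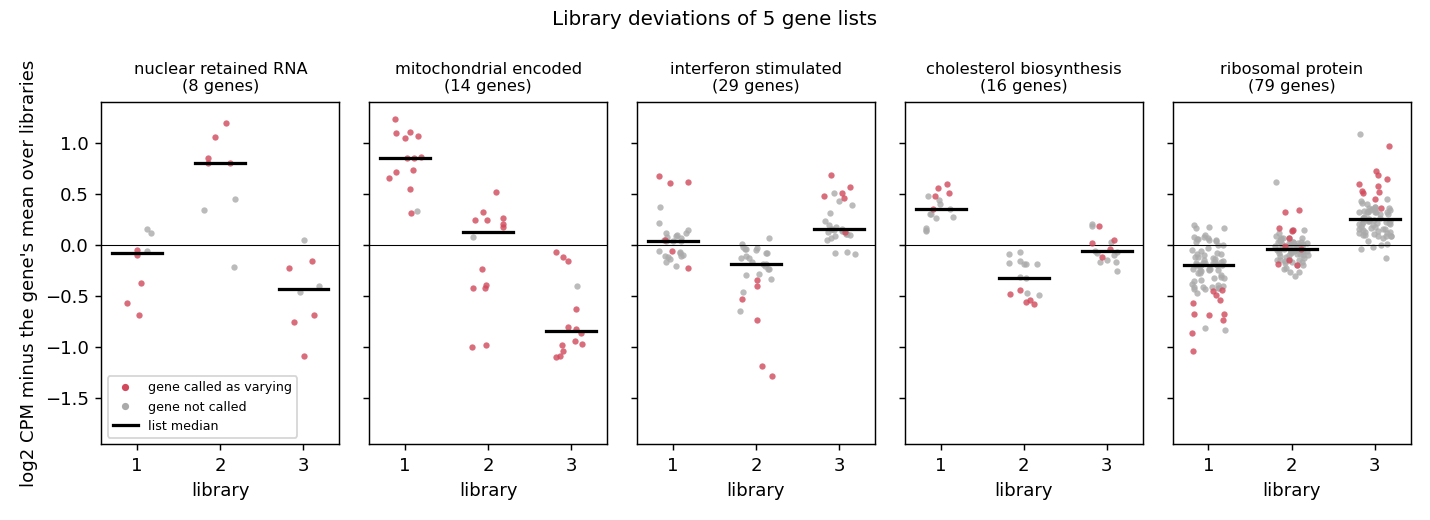
Log2 CPM of each tested gene minus that gene's mean over the 3 libraries, for 5 lists, with genes called as varying in red, other genes in grey and the list median as a black bar. Nuclear retained RNAs stand highest in library 2 for 7 of 8 genes and cholesterol synthesis genes in library 1 for 16 of 16. The cholesterol synthesis genes stand lowest in library 2 for 15 of 16.

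Among single genes of at least 5 TPM, the largest range was that of Gm49369, with log2 CPM of 5.18, 9.83 and 5.44 (chromosome 7, 142371096 to 142382667; edgeR adjusted p = 2.59e-75). It overlaps Ctsd (142375911 to 142388038), so its reads cannot be told from those of Ctsd with certainty, and without replicate 2 its range was 0.26 (edgeR adjusted p = 1.00). Rps12-ps3 (range 3.49), Gm20463 (range 3.38), Gm49207 (range 3.13) and Gm26917 (range 2.65) came next among genes outside the lists, and none of these 4 was called without replicate 1 (edgeR adjusted p from 0.171 to 1.00). Rps12-ps3 is named for a ribosomal protein gene it can share reads with, Gm20463 is annotated as antisense, and Gm49207 had 24.5 TPM in the first quantification and 0 in the second, so these 3 are uncertain. Gm26917, annotated as lincRNA, was not checked for reads shared with other genes. It stayed in the test without small structured, mitochondrial and ribosomal RNA, which dropped ribosomal RNA by annotated class only. Hist1h2ai and Hist1h2br, members of a family of near-identical histone genes, had ranges of 2.78 and 2.59 and were not called in the second quantification (edgeR adjusted p = 1.00 for both). Gm10252 overlaps Ftl1 and Gm37376 overlaps Malat1, and their values are uncertain for that reason.

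The 2 deposited quantifications ranked genes alike, with Spearman's rho across 3474 genes of 0.926, 0.917 and 0.926 in libraries 1, 2 and 3. After centring, 84 genes differed more than 2-fold in each library (43 higher and 41 lower in the second), and 0 of 107 genes of the response and macrophage lists did. The pseudogenes Gm12896 and Gm12895 had 150489 and 150468 TPM in the second quantification and 0 in the first. The microRNA genes Gm23935, Gm24270 and Gm24245 had 127960 TPM each in the second and 0 in the first.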

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

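The check of phiX174, a bacteriophage genome often added to sequencing runs as a control, was chosen only after its counts were seen. Its genome is listed beside the genes and enters no comparison. It had 121095, 59802 and 7317 expected counts in libraries 1, 2 and 3, which is 0.365%, 0.162% and 0.0200% of all counts, and each is above the 3 counts that a count of 0 allows.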

How the results depend on the processing

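The tests without small structured, mitochondrial and ribosomal RNA and those on protein-coding genes, and the small structured RNA share in other settings, were chosen only after the result was seen. Of 81 alternative values of the main results, 68 stayed on the same side of the threshold or within the spread, 9 moved, 3 were weaker, 1 was stronger and 0 reversed. The 4 list comparisons kept direction and call under each alternative run. Detected genes numbered 5930 at a threshold of 5 TPM, fewer by construction. The retained intron difference passed the threshold with the median share (1.82 percentage points, permutation p = 0.0475), and the cause was not tested. Spearman's rho with gene length ran from -0.252 to -0.239 with 1 replicate left out and missed the threshold each time (permutation p up to 0.0641), on less data. Varying genes numbered 89 to 132 with 1 replicate left out and 128 at a threshold of 0.01. In the test of protein-coding genes alone, where fewer genes were tested, 129 varied, against 115 protein-coding genes called in the main test. Lists called among the varying genes numbered 3 to 5 with 1 replicate left out. The nuclear retained RNA share was 0.177% of rescaled TPM, which leaves out the small RNA by construction. It was 0.0214% in the second quantification, where 5 genes at 0 TPM in the first held 68.5% ± 11.5 of TPM. These genes lower all other shares, and whether they account for the whole fall was not tested.

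Among named genes and lists, rescaling moved 108 of 113 TPM values, since it lifts every kept gene. The second quantification moved 102 of 146 values and weakened 4 calls, and its median log2 ratio to the first was -1.13, -1.43 and -2.13 in libraries 1, 2 and 3. Leaving out replicate 1, 2 or 3 weakened 11, 7 and 6 of 149 results, all of them among the 21 calls of varying lists and genes. The rest are levels and shares, which counted as the same within the SD over the 3 libraries. A mean with 1 of the 3 left out cannot leave that SD, so these results could not move and do not show stability. DESeq2 size factors and the lack of a filter each left 21 of 21 in place. DESeq2 size factors kept the calls of 203 of 203 genes. Without the filter 221 genes varied, with 158 of the 203 among them, and in the second quantification 200 did, with 130 of the 188 tested there. The small structured RNA share fell to 18.5% of TPM in the second quantification. There 5 genes at 0 TPM in the first quantification held 56.6%, 69.3% and 79.5% of TPM in libraries 1, 2 and 3. Since TPM are shares, these genes lower the share of all other RNA. Whether they account for the whole fall was not tested. No paired analysis was possible because there is 1 group. Depth limits low genes, such as Nos2 with 7, 2 and 3 counts, and with 3 libraries a 2-fold shift in 1 library was called in 42 of 100 simulated genes.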

Other observations

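The tests on nuclear carry-over, length in the nuclear pattern, an earlier point of the response, fewer responding cells and the rule for pseudogene reads were chosen only after the result was seen, and the genes described first were chosen after their values were seen. The anti-inflammatory cytokine Il10 stood at 141 ± 69.4 TPM (219.7, 88.4 and 115 TPM in libraries 1, 2 and 3; edgeR adjusted p = 0.0377). Il1rn, the interleukin-1 receptor antagonist, stood at 66.5 ± 13.4 TPM, the cytokine Osm at 45.5 ± 5.04 TPM, the angiogenic factor Vegfa at 103 ± 22.7 TPM and the growth factor Csf1 at 38.2 ± 13.0 TPM. The plasminogen activator Plau stood at 62.1 ± 5.63 TPM, Hif1a at 18.3 ± 1.84 TPM, and Slc7a11 and F3 at 2.26 ± 0.266 and 0.433 ± 0.280 TPM. Hbegf stood at 6.74 ± 1.39 TPM and varied between libraries (edgeR adjusted p = 0.00517).

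Gpnmb, a lysosomal membrane protein, stood at 2892 ± 540.1 TPM, osteopontin Spp1 at 1464 ± 322 TPM, the fatty acid binder Fabp5 at 1198 ± 173 TPM, lipoprotein lipase Lpl at 331 ± 64.6 TPM and the scavenger receptor Cd36 at 159 ± 30.2 TPM. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in each library, while Xist stood at 2.92, 6.60 and 4.96 TPM. The labels do not give the sex of the mice.

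Nuclear retained RNAs stood higher in library 2 than in library 3, by a median log2 difference of 1.02 over 8 list genes in scaled counts (random lists -0.21 to 0.26). A candidate explanation is nuclear RNA carried into the cytosolic fraction, and 217 unspliced or unverified transcripts outside the list (the TEC and sense intronic classes) had a median log2 difference of 0.95, where random lists of matched level lay between -0.06 and 0.08. Genomic DNA would raise silent genes too, but 1468 odorant and vomeronasal receptor genes rose by 2.60% of the rise of 3545 genes of these classes, tested or not, in counts per kilobase. Length and this difference had a Spearman's rho of 0.144 across genes, but against random lists matched on length and level (-0.18 to 0.22 for the list, -0.03 to 0.11 for the 217 transcripts) the medians of 1.02 and 0.95 still stood apart, which argues against length as the whole cause. Rn7sk, described above as acting on transcription, and Rpph1 are outside the list. Rn7sk had log2 CPM of 13.80, 13.96 and 11.84 in libraries 1, 2 and 3, and Rpph1 had 13.40, 13.17 and 11.44. Both were also lower in library 3 than in library 2, but stood about as high in library 1. No biological explanation was tested, since the design holds 1 group.

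Interferon stimulated genes stood lower in library 2, by a median log2 difference from the mean of libraries 1 and 3 of -0.28 over 29 genes in scaled counts (random lists -0.08 to 0.07). An earlier point of the response may account for it. The immediate early list was assumed to be higher then, and it differed by 0.022 (random lists -0.08 to 0.08). No other time was analysed here, so the direction this list would take is not known. Its value therefore cannot decide, and an earlier point stays open. Fewer responding cells could lower the early inflammatory list, which differed by -0.20 (random lists -0.07 to 0.07), but so could an earlier point. The value of the early inflammatory list therefore does not tell these explanations apart. The immediate early list was not lower, yet levels without lipid A were not analysed here, so fewer responding cells also stay open. The test first pooled both early lists, whose median fell below the random lists, and was changed to ask for each list separately after that was seen. No explanation was tested for the higher side of the pattern, in which 22 of the 29 interferon stimulated genes were highest in library 3.

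Ribosomal protein mRNAs stood higher in library 3 than in library 1. Their transcripts are short (median 708 bp against 2517 bp for all tested genes), and across genes length and this difference had a Spearman's rho of -0.218, so a length bias could raise them. Against random lists matched on length and level, which lay between -0.06 and 0.16, their median difference of 0.46 still stood apart, which argues against length as the whole cause. Reads shared with pseudogenes could also play a part. Adding the counts of the processed pseudogenes named for 57 of the genes left the median at 0.46. But all 287 processed pseudogenes named for ribosomal protein genes, added or not, held only 1.13% as many counts as the list in library 1. Processed pseudogenes of any name held 0.0950% and 0.0977% of gene expected counts in libraries 1 and 3, against 1.43% and 1.89% for the list. These values argue against counts lost to processed pseudogenes as the whole cause. Pseudogenes of other classes, and pseudogene reads counted on the list's own genes, were not covered, so their part stays open. No biological explanation was tested for this pattern.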
